A study of Homo sapiens and Homo sapiens
Mus musculus with 10 samples.

How the data were processed

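The data were single-cell RNA measurements from 10 samples: 8 libraries of EBs made from 1 human iPSC line (days 13, 15, 17 and 19, with 2 libraries per day) and bone marrow of 2 mice taken 20 weeks after engraftment of EB cells. Per the labels, EB libraries were made with 10x Chromium chemistry v2, processed with Cell Ranger 2.1.1 and aligned to hg19, and marrow libraries were made with chemistry v3.1, processed with Cell Ranger 6.0.0 and aligned to GRCh38 and to mm10. The header of the matrix of day 15 replicate 1 names release 6.0.0 instead, and the marrow headers name Cell Ranger 4. The gene annotation version was not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, which were checked to be whole numbers, for 32738 genes in EBs, 33538 in the human and 31053 in the mouse alignment. The authors also deposited a name for each cell they kept and, for marrow, its species, from Seurat clusters, and how clusters were named and doublets treated was not given in the sources used here.

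The authors' cells and names were used as deposited. All kept EB cells had under 10% mitochondrial UMIs. In 7 EB libraries 98.2 to 99.3% of deposited barcodes were kept, and in day 15 replicate 1 75.8% of 3753. There were 26027 EB cells in 27 classes, with library totals of 43684120 to 76669425 UMIs and median depths of 11122 to 16844 UMIs per cell. Part of the marrow barcodes stood in the cell table in duplicate (6496 of mouse L1 and 4366 of L5), always with the same name and species, and each barcode was counted once, which left 10094 and 9807 cells. Human marrow cells held 14223845 and 8286604 UMIs of the human alignment with medians of 2582 and 1784 per cell, and mouse cells 82331554 and 58981530 UMIs of the mouse alignment with medians of 10104 and 6418. The embedding coordinates in the cell tables were not used here. Raw sequencing reads were not analysed here.

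Genes were tested on UMI counts summed over the kept cells of each library, since cells are not replicates. edgeR 4.0.16 under R 4.3.3 was used with TMM normalization, filterByExpr and a robust quasi-likelihood fit with the day as a factor over all 8 libraries, which leaves 4 residual degrees of freedom. Contrasts were the consecutive days and day 19 against day 13, with a joint test for any day, Benjamini-Hochberg adjustment and a threshold of 0.05. SEs of log2 fold changes and the levels given with them, as CPM of TMM-scaled totals, came from the same fit, while levels by class, in marrow and beside marrow are CPM of unscaled totals. The fit was repeated on cells of the classes MEP and Monocytes together (blood) and of GJA5+ and APLNR+ Endothelium together (endothelium), where every library had at least 20 cells. A joint fit of blood and endothelial sums, with the library as a block, tested whether the day 19 against day 13 change differed between them. The spread between libraries, as a biological coefficient of variation, was 0.123 in whole EBs, 0.112 in blood and 0.119 in endothelium. The tests were tried on simulated data with 200 changed genes. At a log2 change of 1, 68.0% of changed genes were recovered for day 19 against day 13 in whole EBs, 62.0% in blood and 50.0% in endothelium. At a log2 change of 2 these were 81.0%, 90.0% and 85.0%. Of the unchanged genes, 12 of 18735, 17 of 10197 and 12 of 10446 were called. For day 17 against day 15 in whole EBs 22 unchanged genes were called, beside 53 and 86 recovered. In each of these fits false calls were a larger share of the calls than 0.05.

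Lists of genes were fixed for 29 human and 10 mouse cell types and processes, and the 28 human lists with at least 3 measured members were tested in whole EBs with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Several lists share genes or hold genes of other tissues, such as KDR in the endothelial and early mesoderm lists. Genes named from a comparison had an adjusted p under 0.05, a mean log2 CPM of at least 5 and no overlap between the libraries of the days compared. Of these the 8 highest and 8 lowest log2 fold changes were named for day 19 against day 13 in whole EBs, 4 and 4 for consecutive days, and 5 and 5 in blood and in endothelium, leaving out clone-based names, mitochondrial and ribosomal protein genes, XIST and Y-linked genes. From each list up to 4 members past the threshold were taken with the largest change, or the 2 with the smallest p where fewer than 2 passed, and in marrow the 4 with the highest mean level. Lists, comparisons and this rule were fixed in advance. Some genes that the rule selects are not reported here.

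Class shares were tested with an exact permutation test of the between-day F statistic over the 105 distinct splits of the 8 libraries, whose smallest p is 0.00952, adjusted over 27 classes. It is a test of any difference and has no direction. For cells with endothelial and blood-forming transcripts, each cell was thinned to 2000 UMIs at random with a fixed seed. Marrow shares carry 95% Clopper-Pearson intervals. Where 0 counts were seen, 3 counts of the total were taken as the limit. Gene coordinates are those of GENCODE 44 lifted to GRCh37. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 and matplotlib 3.10.9 were used for the rest.

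Alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 tests, no filter on low counts, the replicate number as a block, each library left out in turn, all deposited barcodes, the cells that Scrublet called doublets left out and globin genes left out before normalization. For lists, shares and marrow they were the other list tests, cells with at least 1000 genes, thinning to 1000 or 4000 UMIs or none, a minimum of 1000 UMIs and species thresholds of 80% and 95%. Added after the data were seen were the highest Scrublet scores left out (737 cells), MEP cells alone, GJA5+ Endothelium alone, the block with an estimated list correlation, every line of the marrow cell tables counted, and species by the larger number of UMIs. Scrublet, at its own threshold, called 4 doublets in all 8 EB libraries, and leaving these out tests little. A fit with 1 library left out assumes that the lone library of that day varies like the other days. Genes missing from the EB gene table, such as PECAM1, TRAC, TRBC2, IGHM, IGKC, TPSB2 and SMIM24, could not be measured in EBs.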

Results

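Single-cell RNA was measured in human embryoid bodies (EBs), which are aggregates grown in suspension from 1 human induced pluripotent stem cell (iPSC) line, and in the bone marrow of 2 mice that had received EB cells 20 weeks earlier. The EBs were sampled on days 13, 15, 17 and 19 of culture, with 2 libraries per day. The title of the series names haematopoietic stem and progenitor cells made from iPSCs without transgenes, so the comparisons asked which cell types and genes differed between the days and which human blood cells were present in the recipients. On day 13 the libraries of replicates 1 and 2 held 4663 and 3094 cells with 76669425 and 65498111 unique molecular identifiers (UMIs). The day 15 libraries held 2845 and 3103 cells with 44247942 and 52433801 UMIs, and the day 17 libraries 3931 and 2803 cells with 55278452 and 50471187 UMIs. On day 19 there were 2602 and 2986 cells with 43684120 and 53095494 UMIs. Median depth ran from 11122 to 16844 UMIs per cell across the 8 libraries. Nothing in the labels says that the libraries of a day came from separate cultures, so the p-values measure only the spread between these libraries, and the day cannot be told apart from the preparation of its libraries.

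The first question was which cell types made up the EBs on each day, using the 27 class names that the authors gave to the cells. Shares are means ± SD of n = 2 libraries per day. Mesoderm cells fell from 10.5 ± 2.67% of cells on day 13 to 1.81 ± 0.381% on day 19, and Cardiac Differentiation cells from 3.44 ± 1.53% to 0.285 ± 0.0229%. Neural Crest cells rose from 0.0162 ± 0.0229% on day 13 to 14.5 ± 1.72% on day 15 and stood at 13.0 ± 0.0515% on day 19. Neurons were absent from the counts of day 13, with 0 of 4663 cells, which allows a share of up to 0.0643%, and 0 of 3094 cells, which allows up to 0.0970%. They made up 11.5 ± 0.509% of cells on day 15 and 8.63 ± 0.351% on day 19. Cycling Cells rose from 0.264 ± 0.130% on day 13 to 10.6 ± 0.129% on day 15. Cells named EVT, the abbreviation for extravillous trophoblast, the invasive cells of the placenta, rose from 0.483 ± 0.50% on day 13 to 6.19 ± 0.123% on day 17. These were the 6 of 27 classes past the threshold in an exact permutation test of the spread between days (each p = 0.00952, the smallest that the 105 splits of the libraries can give, and adjusted p = 0.0429). Without adjustment 11 classes had a p under 0.05. No class can go below the smallest p, and a class at that p passed the adjustment only because 6 classes shared it. The 6 calls therefore stood or fell together, whatever the size of each difference. The call rested on single libraries: without day 13 replicate 1 or 2, day 15 replicate 1 or 2, day 17 replicate 2, or day 19 replicate 1 or 2, 0 classes passed, and without day 17 replicate 1, 7 did.

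Blood was held by the classes MEP, which stands for megakaryocyte-erythroid progenitors, and Monocytes. MEP cells made up 2.63 ± 0.0772% of cells on day 13, 1.40 ± 0.253% on day 15, 3.72 ± 1.20% on day 17 and 3.56 ± 0.413% on day 19 (exact permutation p = 0.0571, adjusted p = 0.120). Monocytes were 0.156 ± 0.00812% on day 13 and 1.39 ± 0.262% on day 19 (exact permutation p = 0.0190, adjusted p = 0.0643). The 10 leading genes of this class held 3 of the granulocyte list, PRTN3, MPO and S100A8, and 2 of the monocyte and macrophage list, LYZ and C1QC. Their share among blood cells was 5.60 ± 0.120% on day 13 and 28.2 ± 6.15% on day 19 (exact permutation p = 0.0571). The endothelial classes GJA5+ Endothelium, which expressed the arterial gene DLL4, and APLNR+ Endothelium, which expressed the receptor gene APLNR, together held 8.87 ± 0.799% of cells on day 13, 2.76 ± 0.764% on day 15, 5.48 ± 0.982% on day 17 and 2.25 ± 0.295% on day 19 (exact permutation p = 0.0190). Taken alone, GJA5+ Endothelium was 4.45% of cells on day 13 and 1.39% on day 19 (exact permutation p = 0.20), and APLNR+ Endothelium 4.42% and 0.861% (exact permutation p = 0.0857).

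No other class passed the test, and mean shares on days 13 and 19 with their exact permutation p are given here. Of mesodermal and supporting classes, AGM Mesodermal Progenitor cells, named by the authors after the aorta-gonad-mesonephros region in which blood stem cells first arise, were 8.74% and 1.56% (p = 0.0381, adjusted p = 0.0935), with 0.272% on day 15. The same exact permutation test gave, among the remaining mesodermal and stromal classes, FBLN5+ Mesoderm 5.67% and 2.75% (p = 0.0857), DLK1+ Mesoderm 4.85% and 2.13% (p = 0.114), Arteriolar Pericytes 9.29% and 2.99% (p = 0.114) and Mesenchymal 0.317% and 11.5% (p = 0.0190). For endodermal classes the exact permutation test gave Endoderm 16.4% and 1.26% (p = 0.0762), Endoderm Specification 2.25% and 6.05% (p = 0.0667) and Hepatocytes 3.03% and 2.00% (p = 0.257). The day 13 libraries themselves differed in Endoderm, whose SD was 9.49%. Ectodermal and epithelial classes in the exact permutation test were Ectoderm 5.18% and 4.13% (p = 0.371), Ectoderm differentiation 0.167% and 3.16% (p = 0.0286), Embryonic Epithelium 4.93% and 5.12% (p = 0.714), Epiblast 3.27% and 6.05% (p = 0.0952) and Cranial Differentiation 0% and 0.580% (p = 0.0381). Extraembryonic classes in the exact permutation test were Trophoblast 1.69% and 3.65% (p = 0.0667), Trophoectoderm 1.83% and 0.546% (p = 0.0667) and Amnion 6.07% and 2.56% (p = 0.219). The class ECM Production held 0.185% on day 15 and 0.0192% on day 19 (exact permutation p = 0.429). Cranial Differentiation and ECM Production had 0 cells in both day 13 libraries, which allows shares of up to 0.0643% and 0.0970%. The libraries of a day differed most on days 13 and 17, by 29.2% and 26.6% in class composition. In day 17 replicate 2 the Neural Crest share was 5.17% against 12.1% in replicate 1, and the Amnion share 13.2% against 3.54%.

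**Figure D1:**
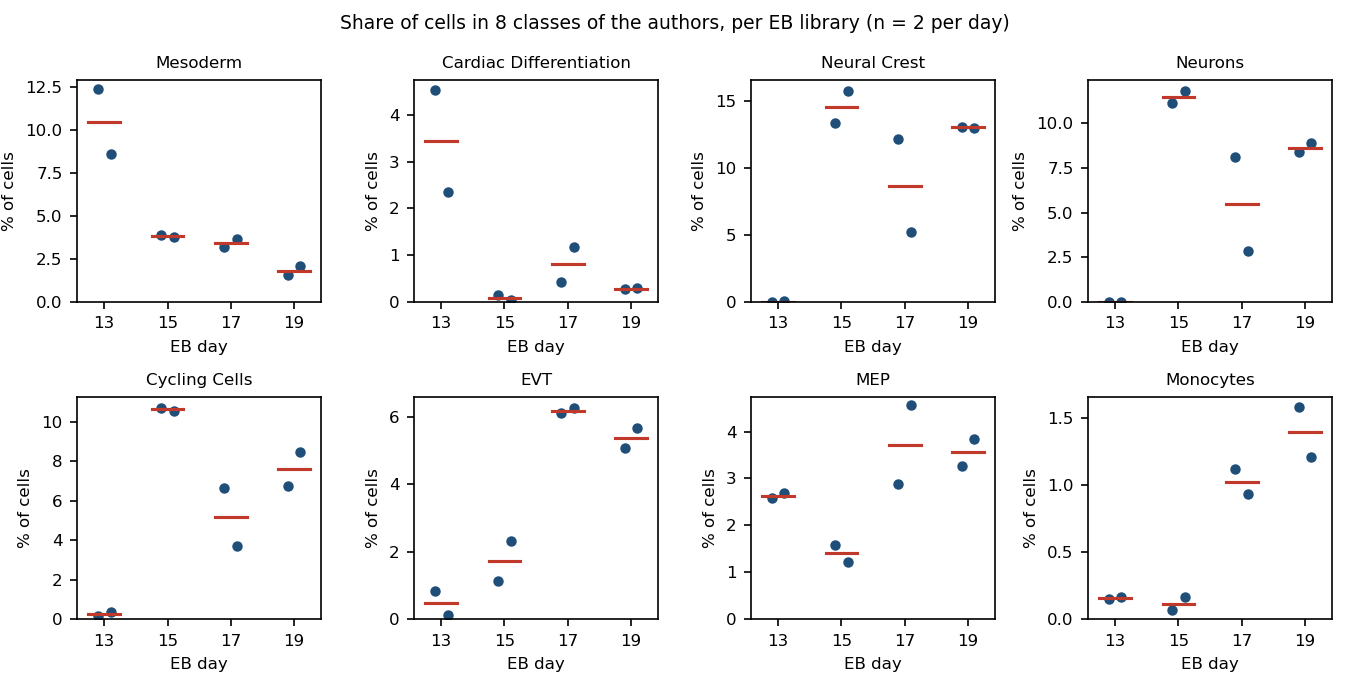
Share of cells in 8 of the authors' classes (percent of cells, vertical axis) by EB day (horizontal axis), with each point 1 library (n = 2 per day) and each bar the mean of a day. Neurons and Neural Crest cells were nearly missing on day 13 and numerous on day 15, while the class named Mesoderm fell after day 13.

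Day 19 against day 13 covered the whole interval of the culture. Of the gene lists tested with camera, those called higher included the neural, megakaryocyte, granulocyte, and monocyte and macrophage lists, and those called lower the early mesoderm, endoderm, muscle and endothelial lists, while none was called with an estimated correlation. Values are log2 fold changes ± SE, and levels are CPM, UMIs of a gene scaled to a fixed total per library after TMM normalization, as mean ± SD of n = 2 libraries per day. S100A9, a calcium-binding protein of neutrophils and monocytes (ENSG00000163220, chromosome 1, 153330330 to 153333499), rose by 5.89 ± 0.81 (adjusted p = 0.00807), from 2.94 ± 1.04 to 176 ± 45.8 CPM. On day 13 67.8% of its UMIs lay in Monocytes, and on day 19 71.3% lay in EVT cells and 22.9% in Monocytes. SST, the neuropeptide somatostatin (ENSG00000157005, chromosome 3, 187386700 to 187388182), rose by 5.53 ± 0.79 (adjusted p = 0.00866), with 91.6% of its day 19 UMIs in Neurons. The platelet chemokine genes PPBP and PF4 rose by 3.85 ± 1.01 (adjusted p = 0.0491) and 3.09 ± 0.48 (adjusted p = 0.0106), and 93.1% and 93.8% of their day 19 UMIs lay in MEP cells. TFAP2B, a transcription factor of neural crest, rose by 3.43 ± 0.53, TTYH1, a membrane protein gene, by 3.19 ± 0.34, and COL2A1, the collagen of cartilage, by 3.19 ± 0.17.

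Among the genes with the largest falls were the metallothionein genes, whose proteins bind zinc and copper: MT1M at -3.15 ± 0.39 (adjusted p = 0.00504, 152 ± 11.9 CPM on day 13 and 17.1 ± 6.11 on day 19), MT1E at -2.54 ± 0.19, MT1G at -2.44 ± 0.28 and MT1H at -2.43 ± 0.39. On day 13 85.4% of MT1M UMIs lay in Mesoderm cells. The apolipoprotein genes APOA2 (ENSG00000158874, chromosome 1, 161192082 to 161193421) and APOC1 fell, at -2.63 ± 0.42 and -2.70 ± 0.41, and APOA2 went from 6508 ± 2923 to 1052 ± 301 CPM. Endoderm cells held 64.1% of APOA2 UMIs on day 13, and Hepatocytes held 72.8% on day 19. IGFBP6, which binds insulin-like growth factors, fell at -2.80 ± 0.37, and CRHBP, a hormone-binding protein gene expressed here in endothelium, at -2.45 ± 0.56. By edgeR, 5404 of 18935 genes passed, 52.0% of them higher on day 19, and DESeq2 called 4519. The count was 2214 without day 19 replicate 1 and 2199 without replicate 2. Of 106 named genes past the threshold, 57 stayed past it with each of the 8 libraries left out in turn and 49 did not, among them PPBP and CRHBP, which were each lost in 6 of the 8 fits.

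**Figure D2:**
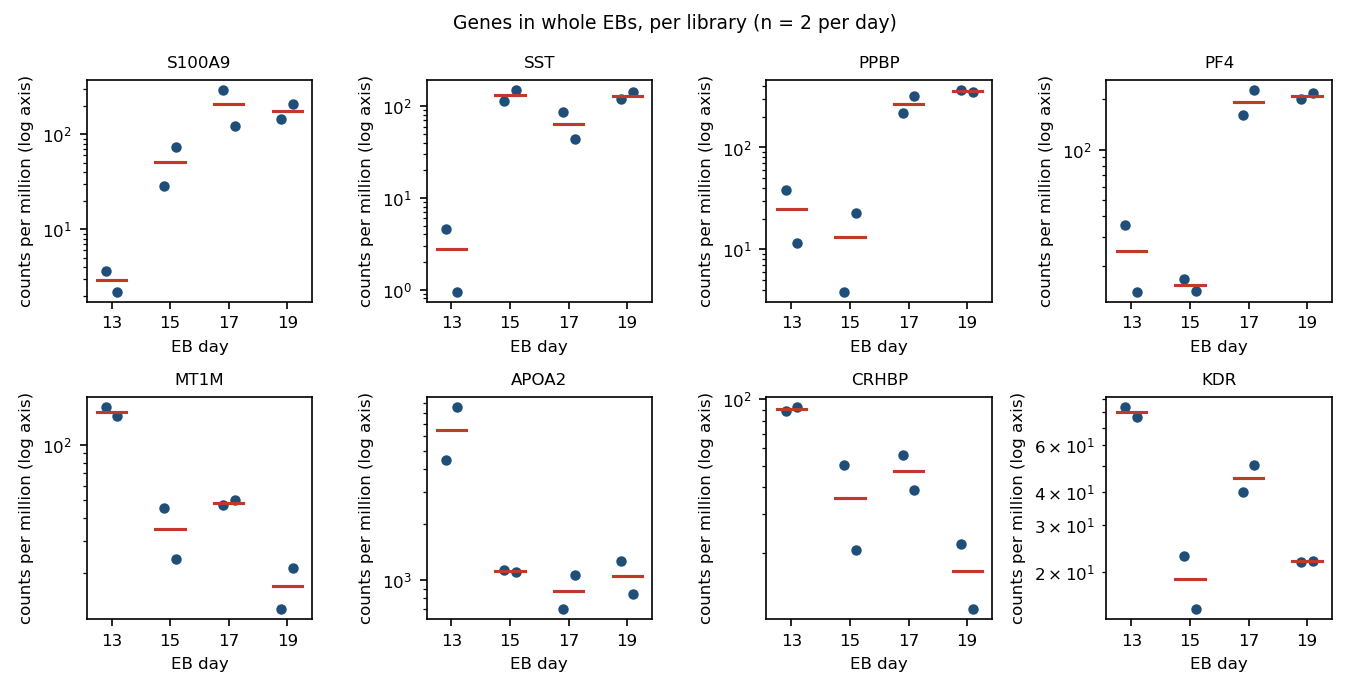
Level of 8 genes in whole EBs (CPM, log vertical axis) by EB day (horizontal axis), with each point 1 library (n = 2 per day) and each bar the mean of a day. S100A9, SST, PPBP and PF4 were higher on day 19 than on day 13 in both libraries, and MT1M, APOA2, CRHBP and KDR were lower.

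Gene lists were fixed before the data were examined. Camera called the megakaryocyte, monocyte and macrophage, granulocyte, and embryonic and fetal globin lists higher in whole EBs on day 19 than on day 13. It called no other blood list tested higher, but lists were not tested against each other. All 8 measured megakaryocyte genes rose, with a median log2 fold change of 2.30 (camera adjusted p = 4.64e-16, and adjusted p = 0.163 with an estimated correlation), among them GP9, part of the platelet receptor for von Willebrand factor, at 3.00 ± 0.16 and TUBB1, the tubulin of platelets, at 2.46 ± 0.20. Of 14 monocyte and macrophage genes 11 rose and 3 did not pass (adjusted over the list alone, 11 higher and 0 lower), with a median of 2.64. Camera gave adjusted p = 5.86e-12, and adjusted p = 0.234 with an estimated correlation. C1QC, a complement gene of macrophages, was at 6.01 ± 1.38 with 97.5% of its day 19 UMIs in Monocytes. Among 8 granulocyte genes 5 rose and 3 did not pass (adjusted over the list alone, 6 higher and 0 lower), including S100A8 at 3.78 ± 0.29 and the granule enzyme gene MPO at 2.80 ± 0.49, with a median of 2.04. For this list camera gave adjusted p = 2.39e-07, and adjusted p = 0.256 with an estimated correlation. CSF3R, the receptor for granulocyte colony-stimulating factor, rose by 1.82 ± 0.15, but 66.8% of its day 19 UMIs lay in EVT cells. The embryonic and fetal globin list had 4 measured genes, of which 2 rose and 2 did not pass (adjusted over the list alone, 2 higher and 0 lower), namely HBG1 at 1.41 ± 0.31 and HBG2 at 1.248 ± 0.12 (camera adjusted p = 0.0206, and adjusted p = 0.334 with an estimated correlation, and 0.0648 without day 19 replicate 2).

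The neural list rose most, with 13 measured genes of which 11 rose and 2 did not pass (adjusted over the list alone, 11 higher and 0 lower) and a median of 3.02. The list test, camera, gave adjusted p = 1.99e-13, and adjusted p = 0.234 with an estimated correlation. Its examples were the neuronal genes ELAVL4 at 7.60 ± 0.76 and DCX at 5.44 ± 0.61, and SOX10, a transcription factor of neural crest, at 4.39 ± 0.34. Of 11 pluripotency genes 6 rose and 5 did not pass (adjusted over the list alone, 8 higher and 1 lower), with SOX2, which is also a neural gene, at 2.04 ± 0.29 and NANOG at 1.16 ± 0.18. In camera this list had adjusted p = 0.00105, and adjusted p = 0.334 with an estimated correlation. Epiblast cells held 58.7% of NANOG UMIs on day 13 and 66.7% on day 19. Of 15 cell cycle genes 6 rose and 9 did not pass (adjusted over the list alone, 8 higher and 0 lower), by small amounts, such as CENPF at 0.67 ± 0.11 and HMGB2 at 0.51 ± 0.08. Camera over these genes gave adjusted p = 0.0206, and adjusted p = 0.507 with an estimated correlation. That list was not called without day 13 replicate 2 (adjusted p = 0.140) or without day 19 replicate 2 (adjusted p = 0.0648).

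Endothelial and mesodermal lists fell over the same interval, while the share of endothelial cells went from 8.87% to 2.25%. Of 14 endothelial genes 11 fell and 3 did not pass (adjusted over the list alone, 1 higher and 12 lower), with a median of -1.36 (camera adjusted p = 3.14e-10, and adjusted p = 0.308 with an estimated correlation), including the receptor genes TEK at -1.95 ± 0.26 and KDR, the main receptor for vascular endothelial growth factor, at -1.87 ± 0.22. Of 10 early mesoderm genes 5 fell and 5 did not pass (adjusted over the list alone, 0 higher and 7 lower), such as HAND1 at -1.91 ± 0.48 and APLNR at -1.86 ± 0.34. Camera gave adjusted p = 9.99e-06, and adjusted p = 0.334 with an estimated correlation. Among 13 arterial genes 1 rose, 4 fell and 8 did not pass (adjusted over the list alone, 1 higher and 4 lower), with the gap junction gene GJA4 at -1.88 ± 0.49 and NOTCH4 at -0.98 ± 0.19. For this list camera gave adjusted p = 0.0206, and adjusted p = 0.507 with an estimated correlation. This call was lost without day 13 replicate 1 (adjusted p = 0.268) or day 19 replicate 2 (adjusted p = 0.0618). For the stem and progenitor list, with 16 genes, 1 rose, 8 fell and 7 did not pass (adjusted over the list alone, 2 higher and 8 lower). The list test, camera, gave adjusted p = 0.00517, and adjusted p = 0.234 with an estimated correlation. Its members moved apart: the pan-leukocyte gene PTPRC rose by 3.27 ± 0.36, while HOPX stood at -1.51 ± 0.12 and PROM1 at -1.34 ± 0.27. In the HOXA list, homeobox genes that pattern the body axis, 10 genes were measured and 3 fell and 7 did not pass (adjusted over the list alone, 0 higher and 5 lower), namely HOXA13 at -1.70 ± 0.35, HOXA9 at -1.30 ± 0.38 and HOXA10 at -0.99 ± 0.28 (camera adjusted p = 0.0183, and adjusted p = 0.507 with an estimated correlation, and 0.266 without day 13 replicate 1).

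Muscle, endoderm and matrix lists fell too. Of 13 muscle genes 6 fell and 7 did not pass (adjusted over the list alone, 0 higher and 8 lower), with the cardiac factor NKX2-5 at -2.87 ± 0.20 and the sarcomere gene TTN at -2.11 ± 0.34. In camera this list had adjusted p = 9.99e-06, and adjusted p = 0.308 with an estimated correlation. Of 14 endoderm and hepatic genes 5 fell and 9 did not pass (adjusted over the list alone, 0 higher and 5 lower), such as APOA1 at -2.39 ± 0.49 and the gut factor CDX2 at -2.04 ± 0.33. Camera over these genes gave adjusted p = 3.01e-05, and adjusted p = 0.378 with an estimated correlation. In the mesenchymal and fibroblast list of 12 genes 1 rose, 4 fell and 7 did not pass (adjusted over the list alone, 2 higher and 7 lower), with FN1 at -1.53 ± 0.23 and LUM at -1.44 ± 0.11 but TWIST1 at 1.68 ± 0.25. Camera gave adjusted p = 0.0148, and adjusted p = 0.334 with an estimated correlation. Of 14 BMP and TGF-beta genes 1 rose, 8 fell and 5 did not pass (adjusted over the list alone, 2 higher and 9 lower), with the inhibitor gene SMAD6 at -1.38 ± 0.23 and the ligand genes TGFB2 at -1.35 ± 0.22 and BMP2 at -1.29 ± 0.21. For this list camera gave adjusted p = 0.00400, and adjusted p = 0.334 with an estimated correlation. Camera with its preset correlation called 16 of 28 lists, 7 higher and 9 lower. With an estimated correlation it called 0, with 5 lists at an unadjusted p under 0.05, and fry called 17.

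The other 12 lists were not called by camera, while fry called 4 of them. Of 13 erythroid genes 3 rose, 3 fell and 7 did not pass (adjusted over the list alone, 3 higher and 3 lower), among them HEMGN at 4.05 ± 0.28 and GATA1 at 0.98 ± 0.19, with a median of -0.29, a mean of 0.19 and camera adjusted p = 0.936. Of 15 genes of the passage from endothelium to blood 3 rose, 6 fell and 6 did not pass (adjusted over the list alone, 3 higher and 6 lower), with GFI1B at 1.64 ± 0.21 and LMO2 at -1.34 ± 0.15 (camera adjusted p = 0.316). Among 7 venous genes 1 rose, 4 fell and 2 did not pass (adjusted over the list alone, 1 higher and 4 lower) (0.249), with NR2F2 at 1.45 ± 0.28. Of 4 adult globin genes 1 rose and 3 did not pass (adjusted over the list alone, 1 higher and 0 lower), HBB at 0.73 ± 0.18 (0.316), of whose UMIs the blood classes held 3.80% on day 13 and 4.74% on day 19. The B lineage list had 9 genes, of which 2 rose and 7 did not pass (adjusted over the list alone, 2 higher and 0 lower), EBF1 at 3.997 ± 0.54 and PAX5 at 1.79 ± 0.47 (0.103). On day 19, 68.0% of EBF1 UMIs lay in Neurons. The T and NK list had 12 genes, of which 3 rose and 9 did not pass (adjusted over the list alone, 3 higher and 0 lower), with CD2 at 3.38 ± 0.28 (0.106). The dendritic list had 6, of which 4 rose and 2 did not pass (adjusted over the list alone, 4 higher and 1 lower), with IRF8 at 1.43 ± 0.36 (0.0913). Of 10 trophoblast and amnion genes 4 rose, 2 fell and 4 did not pass (adjusted over the list alone, 4 higher and 2 lower), with TFAP2A at 1.37 ± 0.18 and IGFBP3 at -1.01 ± 0.13, a median of -0.08 and a mean of 0.27 (0.563).

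Of 11 epithelial genes 2 fell and 9 did not pass (adjusted over the list alone, 0 higher and 2 lower), KRT19 at -1.03 ± 0.26 and EPCAM at -0.65 ± 0.17 (camera adjusted p = 0.326). Of 12 Notch genes 2 rose, 2 fell and 8 did not pass (adjusted over the list alone, 2 higher and 2 lower), with HEY2 at -0.76 ± 0.12 and JAG1 at 0.70 ± 0.21 (0.836). The hypoxia and glycolysis list held 14 genes, of which 2 rose, 1 fell and 11 did not pass (adjusted over the list alone, 1 higher and 0 lower), with ADM at -0.85 ± 0.24 and LDHA at 0.34 ± 0.11 (0.293). Of 13 immediate early and heat shock genes 1 rose, 1 fell and 11 did not pass (adjusted over the list alone, 1 higher and 1 lower), FOSB at 0.64 ± 0.10 and DUSP1 at -0.31 ± 0.06 (0.839). The mast cell and basophil list had 2 measured genes, IL1RL1 at 0.18 ± 0.88 and HDC at 0.09 ± 0.71, too few to test. The median and the fitted direction differed in sign for the erythroid and for the trophoblast and amnion lists, and the endothelial-to-haematopoietic median was -0.46 with a mean of -0.11.

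**Figure D3:**
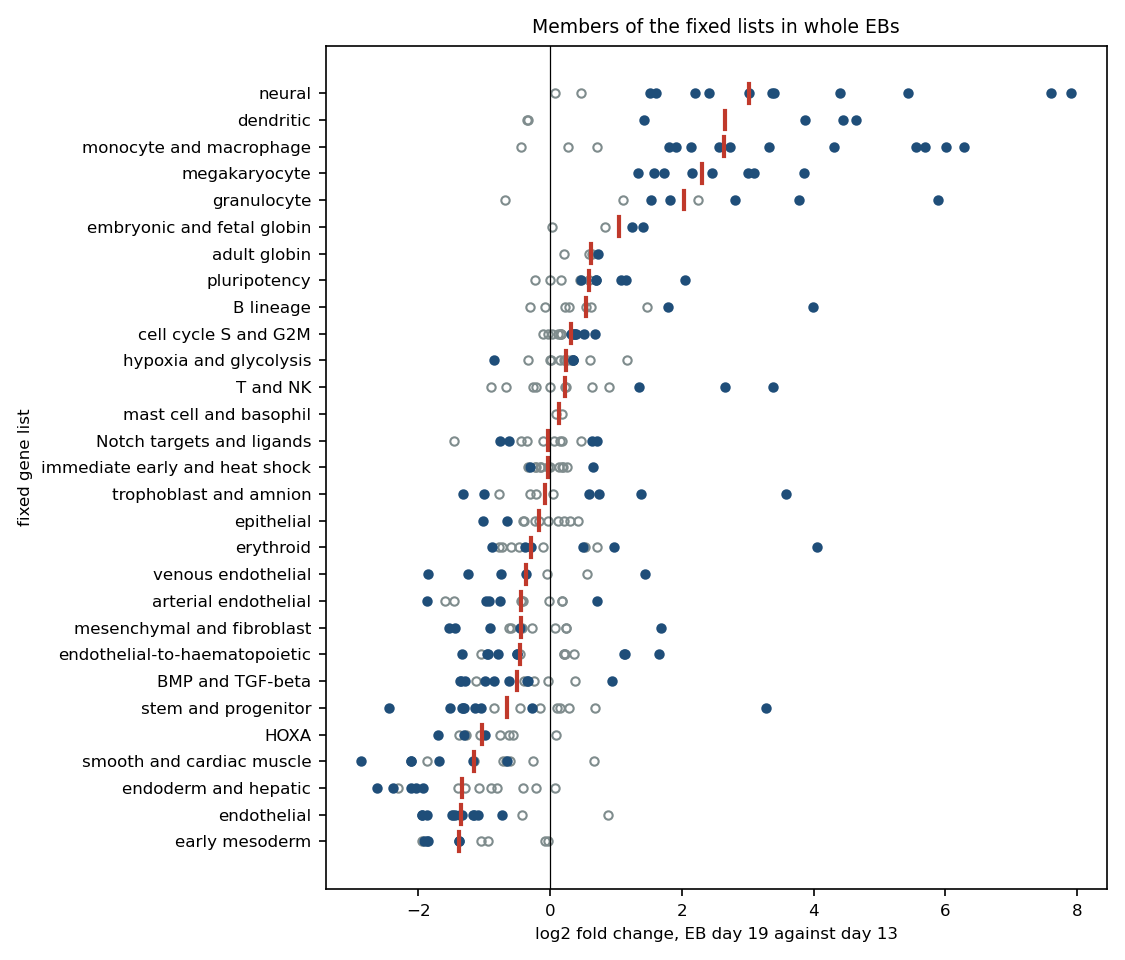
Log2 fold change of day 19 against day 13 in whole EBs (horizontal axis) for each measured member of the fixed gene lists (vertical axis), filled where the adjusted p was under 0.05 and open elsewhere, with a bar at each list's median. The neural list had a median of 3.02 and the early mesoderm list one of -1.38.

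The step from day 13 to day 15 asked when these changes began. By camera the neural list was called higher and the endothelial and early mesoderm lists lower within this step, and none of them with an estimated correlation. SST rose by 5.55 ± 0.79 (adjusted p = 0.00567, 2.76 ± 2.57 to 132 ± 25.4 CPM, n = 2 libraries per day), TFAP2B by 4.53 ± 0.55 and S100A9 by 4.11 ± 0.76. RSPO3, which strengthens Wnt signals, fell at -2.55 ± 0.18 (154 ± 34.8 to 26.3 ± 3.95 CPM), GJA4 at -2.30 ± 0.50, APOA2 at -2.53 ± 0.42 and S100A14 at -2.26 ± 0.49. Of 13 neural genes 11 rose and 2 did not pass (adjusted over the list alone, 12 higher and 0 lower), with a median of 2.95. The list test, camera, gave adjusted p = 3.13e-10, and adjusted p = 0.363 with an estimated correlation. Of 15 cell cycle genes 13 rose and 2 did not pass (adjusted over the list alone, 14 higher and 0 lower) (camera adjusted p = 1.67e-06, and adjusted p = 0.363 with an estimated correlation), and Cycling Cells rose in share. Of 14 endothelial genes 12 fell and 2 did not pass (adjusted over the list alone, 0 higher and 12 lower). In camera this list had adjusted p = 1.67e-06, and adjusted p = 0.363 with an estimated correlation. Of 10 early mesoderm genes 8 fell and 2 did not pass (adjusted over the list alone, 0 higher and 8 lower). Camera over these genes gave adjusted p = 2.49e-06, and adjusted p = 0.363 with an estimated correlation.

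The genes of the passage from endothelium to blood also fell by day 15: of 15 measured, 2 rose, 10 fell and 3 did not pass (adjusted over the list alone, 2 higher and 12 lower), with a median of -0.88. Camera gave adjusted p = 0.000253, and adjusted p = 0.363 with an estimated correlation. Among 13 immediate early genes 11 rose and 2 did not pass (adjusted over the list alone, 11 higher and 0 lower). For this list camera gave adjusted p = 0.000431, and adjusted p = 0.363 with an estimated correlation. Muscle genes went the other way, and of 13 9 fell and 4 did not pass (adjusted over the list alone, 0 higher and 10 lower). The list test, camera, gave adjusted p = 4.4e-05, and adjusted p = 0.363 with an estimated correlation. In all, camera called 16 of 28 lists in this step, 5 higher and 11 lower, and 0 with an estimated correlation, with 2 at an unadjusted p under 0.05, while fry called 16. By edgeR 7634 of 18935 genes passed (3790 higher and 3844 lower on day 15), and DESeq2 called 6340. The count was 4789 without day 15 replicate 1 and 4088 without replicate 2, and the any-day test, with 7763 genes, gave 4714 and 4284. Of the genes named for this step, S100A9, GJA4 and S100A14 lost the call in 1 or more of the 8 fits without 1 library.

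Between day 15 and day 17 camera called the megakaryocyte, myeloid and endothelial lists higher and the cell cycle list lower, and none of them with an estimated correlation. PPBP rose by 4.32 ± 1.05 (adjusted p = 0.0458, 13.3 ± 13.3 to 268 ± 72.4 CPM, n = 2 libraries per day) and PF4 by 3.65 ± 0.50. So did GATA3, a transcription factor of trophoblast and T cells, by 1.66 ± 0.27. SERPINA1, a protease inhibitor of liver, fell at -2.05 ± 0.38, RCOR2 at -1.47 ± 0.23, and the amino acid synthesis genes PSAT1 and ASNS at -1.30 ± 0.10 and -1.26 ± 0.12. All 8 megakaryocyte genes rose, with a median of 2.36. In camera this list had adjusted p = 3.11e-23, and adjusted p = 0.124 with an estimated correlation. Of 14 monocyte and macrophage genes 5 rose and 9 did not pass (adjusted over the list alone, 5 higher and 0 lower). Camera over these genes gave adjusted p = 6.03e-09, and adjusted p = 0.183 with an estimated correlation. Of 8 granulocyte genes 4 rose and 4 did not pass (adjusted over the list alone, 6 higher and 0 lower). Camera gave adjusted p = 3.52e-07, and adjusted p = 0.183 with an estimated correlation. Of 15 genes of the passage from endothelium to blood 9 rose and 6 did not pass (adjusted over the list alone, 10 higher and 0 lower). For this list camera gave adjusted p = 3.37e-09, and adjusted p = 0.183 with an estimated correlation. Of 14 endothelial genes 7 rose and 7 did not pass (adjusted over the list alone, 10 higher and 0 lower). The list test, camera, gave adjusted p = 1.06e-06, and adjusted p = 0.330 with an estimated correlation.

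In the same step, of 15 cell cycle genes 11 fell and 4 did not pass (adjusted over the list alone, 0 higher and 13 lower), with a median of -0.43. In camera this list had adjusted p = 2.57e-07, and adjusted p = 0.292 with an estimated correlation. Of 13 immediate early genes 8 fell and 5 did not pass (adjusted over the list alone, 0 higher and 9 lower). Camera over these genes gave adjusted p = 4.19e-05, and adjusted p = 0.266 with an estimated correlation. Neural genes had a median of -0.61, and of 13 2 fell and 11 did not pass (adjusted over the list alone, 0 higher and 2 lower) (camera adjusted p = 0.00143, and adjusted p = 0.359 with an estimated correlation). The Neurons share was 11.5 ± 0.509% on day 15 and 5.45 ± 3.73% on day 17, and the low library on day 17 was replicate 2. Camera called 19 of 28 lists, 14 higher and 5 lower, and 0 with an estimated correlation, with 5 at an unadjusted p under 0.05, while fry called 16. By edgeR 4454 genes passed (2318 higher and 2136 lower on day 17), and DESeq2 called 4076. The count was 1757 without day 15 replicate 1, 1116 without day 15 replicate 2 and 1749 without day 17 replicate 2. PPBP lost the call in 7 of 8 fits without 1 library, SERPINA1 in 4, PF4 in 2 and GATA3 in 1.

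From day 17 to day 19, CD34, the surface marker of endothelium and blood progenitors, fell at -1.24 ± 0.10 (adjusted p = 0.00802), n = 2 libraries per day. The only other gene past the threshold was AC011526.1, a gene with a clone-based name, at -1.62 ± 0.13 (adjusted p = 0.00802). Both were named after their values were seen, since none met the naming rule. CD34 had fallen by day 15, at -1.246 ± 0.10, and had risen from day 15 to day 17, at 1.16 ± 0.10. Endothelial genes had a median of -1.04, with 0 of 14 past the threshold over all genes and 12 lower adjusted over the list alone (camera adjusted p = 2.54e-26, and adjusted p = 0.138 with an estimated correlation). Of 16 stem and progenitor genes 1 fell and 15 did not pass (adjusted over the list alone, 0 higher and 4 lower) (camera adjusted p = 9.2e-08, and adjusted p = 0.116 with an estimated correlation). Neural genes had a median of 0.81, with 3 of 13 higher adjusted over the list alone (camera adjusted p = 5.83e-08, and adjusted p = 0.247 with an estimated correlation). By edgeR 2 genes passed and 2015 had an unadjusted p under 0.05, while DESeq2 called 333. The edgeR count was 59 without day 13 replicate 1, 74 without day 13 replicate 2, 6 and 19 without day 15 replicates 1 and 2, 426 without day 17 replicate 1, and 0 without day 17 replicate 2 or either day 19 replicate. Camera called 16 of 28 lists in this step, 5 higher and 11 lower, and 0 with an estimated correlation, with 4 at an unadjusted p under 0.05, and fry called 0.

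Changes within blood cells were separated from changes in their share by summing the MEP and Monocytes cells of each library. Between day 13 and day 19 megakaryocyte, monocyte and granulocyte genes were among those that rose within these cells, and 2 erythroid genes fell. CCL5, a chemokine of T cells and platelets, rose by 3.90 ± 0.49 (adjusted p = 0.00816, 9.69 ± 8.64 to 149 ± 44.8 CPM, n = 2 libraries per day). S100A8 and S100A9 rose by 3.29 ± 0.57 and 3.23 ± 0.55 (adjusted p = 0.0490 and 0.0459), PLAC8 by 3.02 ± 0.48, and IL8, a chemokine that draws neutrophils, by 2.99 ± 0.27. GYPB, a glycophorin of the red cell membrane (ENSG00000250361, chromosome 4, 144917257 to 144940533), fell at -1.64 ± 0.14 (412 ± 19.8 to 132 ± 32.7 CPM). Others that fell were CRYM at -1.59 ± 0.20, GDF15 at -1.45 ± 0.29, MT1E at -1.39 ± 0.15 and PRAC1 at -1.34 ± 0.19. Blood classes held 0.614% of MT1E UMIs on day 13, against 78.1% in Mesoderm, and 1.09% of GDF15 UMIs, and RNA from other cells was not tested for these genes. Of S100A9 UMIs on day 19, 25.3% lay in blood classes and 71.3% in EVT cells. By edgeR 814 of 10397 genes passed, 76.0% of them higher on day 19, and DESeq2 called 434. The count was 518 without day 13 replicate 1, 242 without day 13 replicate 2 and 353 without day 19 replicate 1. Across all days 1257 genes changed by edgeR and 711 by DESeq2. Of 52 named genes past the threshold 17 kept the call with each library left out in turn, and S100A8 and S100A9 each lost it in 6 of 8 fits and PLAC8 in 4.

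Among 8 megakaryocyte genes 5 rose and 3 did not pass (adjusted over the list alone, 7 higher and 0 lower), with a median of 1.55 (camera adjusted p = 4.72e-10, and adjusted p = 0.269 with an estimated correlation), including GP9 at 1.95 ± 0.19 (176 ± 53.8 to 680.4 ± 91.0 CPM), the collagen receptor gene GP6 at 1.68 ± 0.28 and TUBB1 at 1.42 ± 0.26. Of 13 monocyte and macrophage genes 7 rose and 6 did not pass (adjusted over the list alone, 13 higher and 0 lower) (camera adjusted p = 2.33e-13, and adjusted p = 0.269 with an estimated correlation), with TYROBP, an adaptor of myeloid receptors, at 1.95 ± 0.28. CD14 and FCGR3A had 0 UMIs on day 13 and were at least 5.40-fold and at least 4.81-fold higher on day 19, against a floor of 3 counts over the day. With these at their bound, the list's median was 2.32. Of 7 granulocyte genes 3 rose and 4 did not pass (adjusted over the list alone, 5 higher and 0 lower), with the granule gene AZU1 at 1.34 ± 0.32 (camera adjusted p = 5.68e-05, and adjusted p = 0.418 with an estimated correlation). Monocytes went from 5.60% to 28.2% of blood cells between the days. Of 6 T and NK genes 3 rose and 3 did not pass (adjusted over the list alone, 4 higher and 0 lower), CD2 at 2.44 ± 0.18, CD4 at 3.30 ± 0.63 and IL7R at 2.62 ± 0.77 (camera adjusted p = 5.82e-05, and adjusted p = 0.269 with an estimated correlation). Of 12 immediate early genes 4 rose and 8 did not pass (adjusted over the list alone, 5 higher and 1 lower), with JUNB at 1.57 ± 0.26 (camera adjusted p = 0.0146, and adjusted p = 0.430 with an estimated correlation).

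Erythroid genes in blood cells moved apart: of 11 1 rose, 2 fell and 8 did not pass (adjusted over the list alone, 1 higher and 3 lower), with HEMGN at 3.14 ± 0.28 against GYPB and the erythroid factor KLF1 at -1.31 ± 0.32 (camera adjusted p = 0.00949, and adjusted p = 0.430 with an estimated correlation). Of 10 endothelial genes 2 fell and 8 did not pass (adjusted over the list alone, 2 higher and 4 lower), KDR at -1.99 ± 0.35 and ECSCR at -1.75 ± 0.31 (camera adjusted p = 0.00949, and adjusted p = 0.430 with an estimated correlation). Of 5 muscle genes 2 fell and 3 did not pass (adjusted over the list alone, 0 higher and 2 lower), ACTA2 at -1.39 ± 0.31 and MYL4 at -0.87 ± 0.15 (camera adjusted p = 0.00357, and adjusted p = 0.269 with an estimated correlation). Of 8 endoderm genes 1 fell and 7 did not pass (adjusted over the list alone, 1 higher and 3 lower), TTR at -0.94 ± 0.20 (camera adjusted p = 0.0146, and adjusted p = 0.430 with an estimated correlation). Of 8 epithelial genes 1 fell and 7 did not pass (adjusted over the list alone, 0 higher and 1 lower), KRT18 at -0.78 ± 0.17 (camera adjusted p = 0.0170, and adjusted p = 0.457 with an estimated correlation). Camera called 10 of 25 lists, with an estimated correlation it called 0 with 4 at an unadjusted p under 0.05, and fry called 0.

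In MEP cells alone, a comparison added after the data were seen, camera did not call the erythroid list (adjusted p = 0.0714), nor the endothelial (adjusted p = 0.282), T and NK (adjusted p = 0.0823), immediate early (adjusted p = 0.0618) and epithelial (adjusted p = 0.0791) lists. The other 5 were called there: granulocyte (camera adjusted p = 1.24e-17, and adjusted p = 0.0190 with an estimated correlation), megakaryocyte (adjusted p = 3.1e-15, and adjusted p = 0.219 with an estimated correlation) and monocyte and macrophage (adjusted p = 2.83e-05, and adjusted p = 0.356 with an estimated correlation) higher. Endoderm (adjusted p = 0.0157, and adjusted p = 0.571 with an estimated correlation) and muscle (adjusted p = 0.0491, and adjusted p = 0.386 with an estimated correlation) were called lower. With the level in each class held constant, the larger share of Monocytes gives megakaryocyte genes a median of -0.41.

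The remaining lists were not called in blood cells. Of 15 genes of the passage from endothelium to blood 1 rose, 2 fell and 12 did not pass (adjusted over the list alone, 3 higher and 4 lower), with the progenitor factors MYB at -1.30 ± 0.27 and GATA2 at -1.20 ± 0.17 but GFI1B at 0.71 ± 0.14, a median of 0.09 and a mean of -0.10. Of 13 stem and progenitor genes 1 rose, 2 fell and 10 did not pass (adjusted over the list alone, 1 higher and 2 lower), with PTPRC at 2.27 ± 0.51 and CRHBP at -1.95 ± 0.53. None of the 4 embryonic and fetal globin genes passed, with HBE1 at -1.105 ± 0.54 (adjusted p = 0.354). Of 4 adult globin genes 1 fell and 3 did not pass (adjusted over the list alone, 0 higher and 1 lower), HBD at -0.62 ± 0.14, of whose UMIs the blood classes held 2.72% on day 13 and 3.61% on day 19. Of 8 BMP and TGF-beta genes 3 rose and 5 did not pass (adjusted over the list alone, 3 higher and 0 lower), with ID2 at 0.83 ± 0.13. Of 8 pluripotency genes 2 fell and 6 did not pass (adjusted over the list alone, 0 higher and 2 lower), with DPPA4 at -1.12 ± 0.26. Of 11 mesenchymal genes 2 rose and 9 did not pass (adjusted over the list alone, 2 higher and 1 lower), with VIM at 0.53 ± 0.14. In 4 further lists 1 gene passed: IRF8 at 2.85 ± 0.72 (dendritic), HES4 at -1.104 ± 0.24 (Notch), EPHB4 at -1.62 ± 0.48 (venous) and TFAP2A at 1.83 ± 0.45 (trophoblast), and the only early mesoderm gene to pass was KDR. No gene of the cell cycle, arterial, hypoxia, neural or B lineage lists passed.

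**Figure D4:**
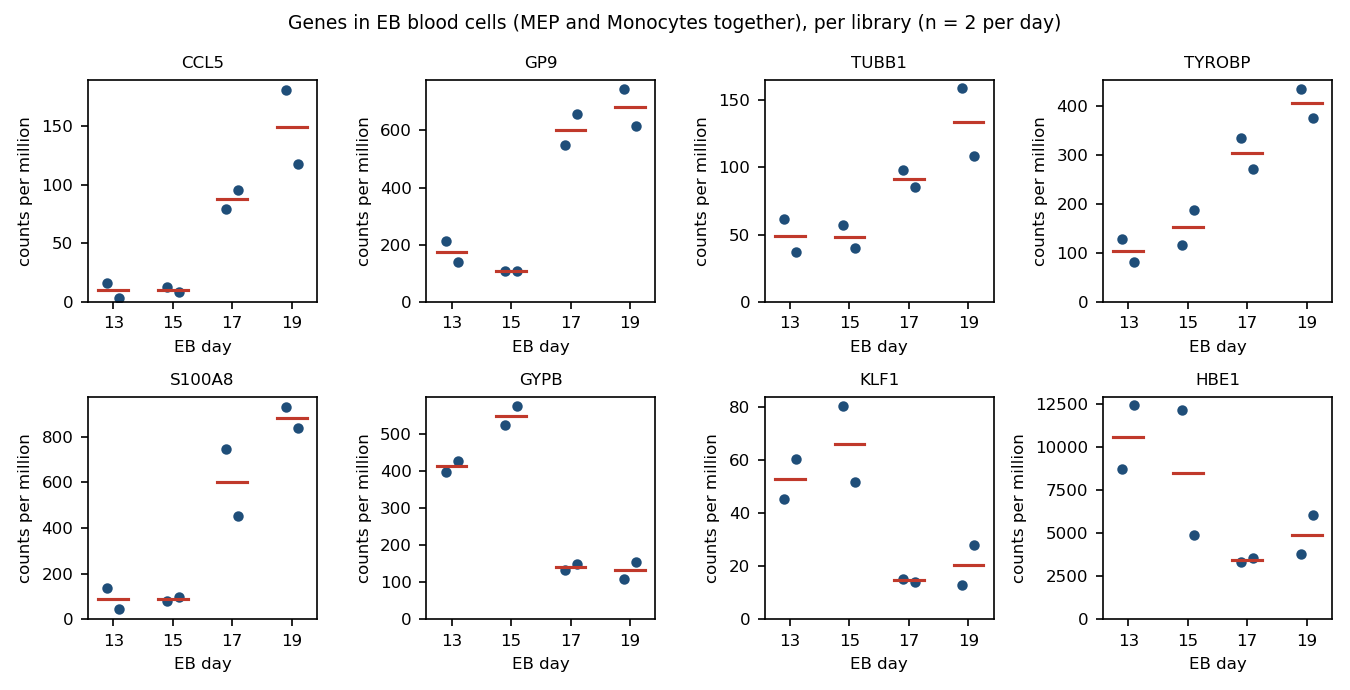
Level of 8 genes in EB blood cells, MEP and Monocytes together (CPM as in the comparisons, vertical axis), by EB day (horizontal axis), with each point 1 library (n = 2 per day) and each bar the mean of a day. GP9 was 214 and 138 on day 13 and 745 and 616 on day 19, and GYPB was lower on day 19 in both libraries.

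Endothelial cells, the source of blood cells in development, were summed in the same way over the GJA5+ and APLNR+ Endothelium classes. GJA5+ cells were 281 of 440 and 89 of 257 of them on day 13, and 41 of 64 and 36 of 61 on day 19. The list tests were not repeated in either class alone. They therefore do not separate a change in this mix from change within a class. Fewer genes passed here, and liver-type transcripts were among those that fell. OLFML3, a secreted glycoprotein gene (ENSG00000116774, chromosome 1, 114522013 to 114578194), rose by 2.28 ± 0.24 (adjusted p = 8.42e-05, 16.9 ± 4.67 to 81.0 ± 18.9 CPM, n = 2 libraries per day). In GJA5+ Endothelium alone, a comparison added after the data were seen, its value was -0.50. Of all genes named in endothelium, 56 kept their side of the threshold there, 1 lost the call, 1 gained it and 1 reversed. PLP2 rose by 2.04 ± 0.24, GPR116 by 1.78 ± 0.24, BAALC by 1.39 ± 0.24 and TSPAN2 by 1.35 ± 0.26. APOA2 fell at -2.96 ± 0.25 (428 ± 149.8 to 55.0 ± 6.31 CPM), the apoptosis gene BIK at -1.79 ± 0.27, GDF15 at -1.72 ± 0.23, the transport protein gene TTR at -1.55 ± 0.23 and NAT14 at -1.32 ± 0.25. Whole-EB levels of APOA2 fell over the same days, and Endoderm and Hepatocytes held most of its UMIs. The endothelial classes held 0.442% of TTR, 6.29% of GDF15 and 2.11% of OLFML3 UMIs on day 13. By edgeR 44 of 10646 genes passed, 33 of them higher on day 19, 1197 had an unadjusted p under 0.05, and DESeq2 called 52. The count was 109 without day 13 replicate 1 and 12 without day 19 replicate 1. Over all days 146 genes passed, 345 without day 13 replicate 1, 42 without day 17 replicate 1 and 83 without day 17 replicate 2. Of 14 named genes past the threshold 4 kept the call with each library left out in turn.

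Of 14 endothelial genes 1 rose and 13 did not pass (adjusted over the list alone, 3 higher and 0 lower), CDH5, the cadherin of endothelial junctions, at 0.68 ± 0.14 (adjusted p = 0.0374, 190.2 ± 39.9 to 306 ± 27.5 CPM), with a list median of 0.29 (camera adjusted p = 0.000429, and adjusted p = 0.284 with an estimated correlation). Of 13 arterial genes 1 rose and 12 did not pass (adjusted over the list alone, 2 higher and 0 lower), NOTCH4 at 0.74 ± 0.15 (camera adjusted p = 0.00147, and adjusted p = 0.404 with an estimated correlation). The calls of CDH5 and NOTCH4 were each lost in 5 of the 8 fits without 1 library. Of 11 stem and progenitor genes 1 rose and 10 did not pass (adjusted over the list alone, 2 higher and 0 lower), BAALC (camera adjusted p = 0.00137, and adjusted p = 0.215 with an estimated correlation). Of 13 hypoxia genes 1 rose and 12 did not pass (adjusted over the list alone, 1 higher and 0 lower), the glucose transporter gene SLC2A1 at 0.89 ± 0.17 (camera adjusted p = 0.00147, and adjusted p = 0.325 with an estimated correlation). Of 10 Notch genes none passed, and the list was called higher (camera adjusted p = 0.0159, and adjusted p = 0.384 with an estimated correlation). Of 8 endoderm and hepatic genes 2 fell and 6 did not pass (adjusted over the list alone, 1 higher and 5 lower), with a median of -1.41 (camera adjusted p = 5.63e-12, and adjusted p = 0.0733 with an estimated correlation).

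Lists called lower in endothelial cells without any member past the threshold were the cell cycle list of 15 genes, with a median of -0.42 (camera adjusted p = 6.05e-06, and adjusted p = 0.284 with an estimated correlation), and the epithelial list of 7 (camera adjusted p = 0.000429, and adjusted p = 0.284 with an estimated correlation). The early mesoderm list of 6 (camera adjusted p = 0.00466, and adjusted p = 0.284 with an estimated correlation) and the muscle list of 7 (camera adjusted p = 0.00511, and adjusted p = 0.322 with an estimated correlation) were lower in the same way. So was the BMP and TGF-beta list of 11, with 2 members lower adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.284 with an estimated correlation). EBF1, of the B lineage list, rose by 2.34 ± 0.43. Camera called 11 of 21 lists, with an estimated correlation it called 0 with 3 at an unadjusted p under 0.05, and fry called 0. THY1, with the next smallest p of the stem and progenitor genes after BAALC, was at 0.46 ± 0.15 and did not pass. No member passed in the other lists, from which the values with the smallest p were GATA2 at -0.41 ± 0.17 for the passage to blood, HBG1 at 2.73 ± 0.62 for globins, and S100A9 at 3.75 ± 0.88 (adjusted p = 0.0752) for granulocytes.

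Cells with endothelial and blood-forming transcripts together were counted without using the classes, as cells with a UMI of CDH5 and of RUNX1, the transcription factor needed for blood to arise from endothelium. PECAM1 is not in the gene table of the EB files, so CDH5 alone stood for endothelium. With every cell thinned to 2000 UMIs, both transcripts were seen in 2 of 4663 and 2 of 3094 cells on day 13, 1 of 2845 and 0 of 3103 on day 15, 0 of 3931 and 1 of 2803 on day 17, and 0 of 2602 and 0 of 2986 on day 19. The counts of 0 allow shares of up to 0.0967%, 0.0763%, 0.115% and 0.100% of cells with both transcripts at this depth, in the order given. The day 15 cell was 1 of 316 Neurons, a class outside the endothelial and blood classes. Whether Neurons make RUNX1 themselves was not tested, so they are no sure measure of background. No difference between days was detectable (exact permutation p = 0.20). At the same depth CDH5 was seen in 29.6 to 51.1% of cells of the endothelial classes and RUNX1 in 12.3 to 22.8% of cells of the blood classes. In Neurons CDH5 was seen in 0 to 1.27% and RUNX1 in 0 to 1.83% of cells. At full depth 0.0967 to 1.49% of all cells held both, against 0 to 1.27% of Neurons. Libraries had median depths of 11122 to 16844 UMIs, Neurons of 9020.5 to 12953. Full-depth shares within the endothelial classes are not given here, so endothelium itself is not set against Neurons.

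In the recipients, the question was which human cells were present 20 weeks after engraftment. Human cells, as named by the authors, made up 31.1% of 10094 cells in mouse L1 (95% exact binomial interval 30.2 to 32.1%) and 25.8% of 9807 cells in mouse L5 (24.9 to 26.7%). There was 1 group of 2 mice and no test was made, and intervals and floors cover counting error only. B lymphocytes were 71.2% (69.6 to 72.8%) of 3143 human cells in L1 and 60.7% (58.8 to 62.6%) of 2531 in L5, and pre-B lymphocytes 19.9% (18.5 to 21.3%) and 18.7% (17.2 to 20.3%). The 10 leading genes of pre-B lymphocytes held 1 of the B lineage list, DNTT, and 2 of the endothelial list, EGFL7 and ERG. Monocytes were 5.70% (4.91 to 6.56%) and 9.28% (8.18 to 10.5%), and the 10 leading genes of that class held 4 of the granulocyte list, S100A8, S100A9, PRTN3 and AZU1, and 1 of the monocyte and macrophage list, LYZ. Mast cells were 1.62% (1.21 to 2.13%) and 2.65% (2.06 to 3.35%), and plasmacytoid cells 1.27% (0.911 to 1.73%) and 2.61% (2.02 to 3.31%). T lymphocytes were 4 cells in L1, 0.127% (0.0347 to 0.326%), and 81 in L5, 3.20% (2.55 to 3.96%). Early erythroid cells were 4 in L1, 0.127% (0.0347 to 0.326%), and 67 in L5, 2.65% (2.06 to 3.35%). The median share of UMIs aligned to the human genome was 76.5% and 79.1% in human cells and 16.03% and 20.01% in mouse cells of L1 and L5. A threshold of 80% left 0.555% and 14.3% human among the cells it could assign.

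**Figure D5:**
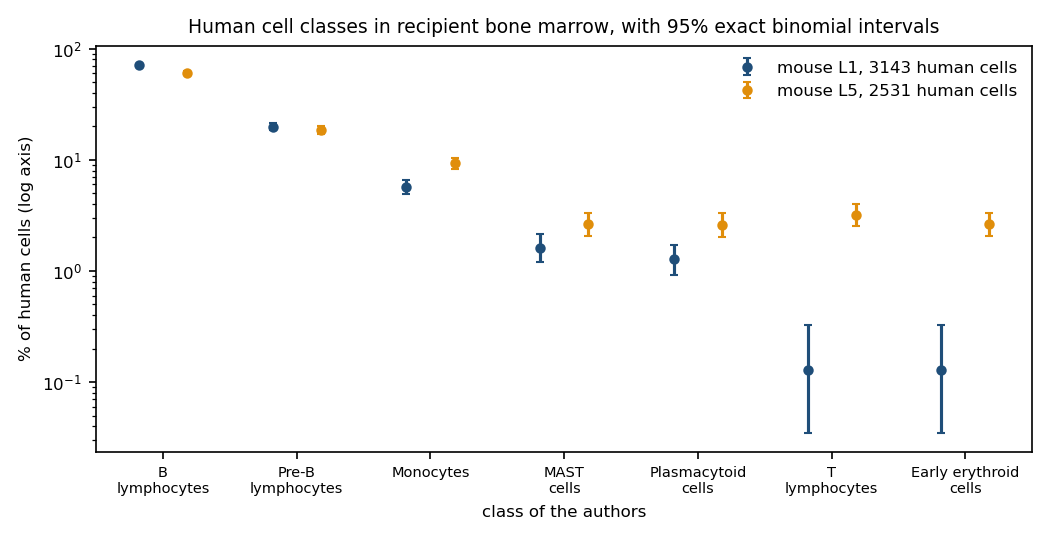
Share of each human class (percent of human cells, log vertical axis) by class of the authors (horizontal axis) in recipient bone marrow, with points for mice L1 (3143 human cells) and L5 (2531) and bars for 95% exact binomial intervals. T lymphocytes and early erythroid cells were 0.127% of human cells in L1 and 3.20% and 2.65% in L5.

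Human marrow cells carried the transcripts of these lineages, given as CPM of the human alignment in L1 and L5. The immunoglobulin heavy chain gene IGHM was at 3668 and 3736, IGKC at 1584 and 2000, the receptor subunit gene CD79B at 2076 and 2239 and the surrogate light chain gene IGLL1 at 2066 and 2178. DNTT, the enzyme that adds bases during receptor gene rearrangement, was at 2681 and 2698 in pre-B and 51.2 and 42.2 in B lymphocytes. Myeloid genes were led by LYZ at 1574 and 1472 and S100A9 at 1603 and 1515, and S100A8 was at 1026 and 338. The mast cell tryptase genes TPSB2 and TPSAB1 were at 218 and 329 and at 144 and 263, and in mast cells TPSAB1 reached 14432 and 22320. Of dendritic genes, TCF4 was at 682 and 619.8 and GZMB at 62.1 and 156, and of T cell genes TRBC2 at 70.7 and 147 and TRAC at 14.3 and 84.1. The most abundant members of the stem and progenitor list were PTPRC at 278 and 267, MSI2 at 246 and 186 and CD164 at 111 and 133. PTPRC is a pan-leukocyte gene, and the authors named no human class as stem or progenitor cells in marrow. These levels therefore do not show that such cells were present. Of the passage from endothelium to blood MYB was at 206 and 186. Of HOXA genes, HOXA10 was at 10.3 and 8.69 and HOXA9 at 7.17 and 4.71, where the mouse cells of the same libraries gave 3.95 and 6.25 for HOXA9 and barcodes under 50 UMIs gave 10.1 and 8.56, above the human cells in both mice. The chemokine receptor gene CXCR4, which holds blood cells in the marrow, was at 1323 and 1290.

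Adult globins in the human cells were HBB at 7471 and 28998 CPM and HBA2 at 187 and 3349 CPM in L1 and L5, and the erythroid gene AHSP at 34.9 and 283. Mouse cells aligned to the human genome gave 308679 and 365493 CPM of HBB. HBE1, the embryonic globin, had 0 UMIs in both mice, which allows up to 0.211 and 0.362 CPM. HBZ, another embryonic globin, was at 35.7 and 3.26 CPM (508 and 27 UMIs), below the mouse cells aligned to the human genome (446 and 74.1) and the empty droplets (315 and 57.8), which here are barcodes under 50 UMIs. The fetal globins HBG2 and HBG1 had 0 UMIs in L1, which held 4 early erythroid cells. In L5 they had 34 and 17 UMIs, all in the early erythroid class of 67 cells. Over all human cells of L5 this was 4.10 and 2.05 CPM, where empty droplets of L5 gave 4.28 and 2.14. Human cells outside that class held none of these UMIs, so this comparison does not give the level within it. The remaining lists gave, as their most abundant gene, PLEK at 64.9 and 70.7 (megakaryocyte), MKI67 at 314 and 364 (cell cycle, after HMGB2 at 1202 and 1147, for which mouse cells gave 3272 and 1304 and empty droplets 2017 and 1133), JUNB at 568 and 1069 (immediate early), ENO1 at 414 and 505 (glycolysis), ID2 at 239.8 and 300.2 (BMP), NRARP at 13.4 and 21.8 (Notch), VIM at 1616 and 2072 (mesenchymal), and TTN at 62.6 and 51.6 with MYL4 at 59.9 and 101 (muscle). Most abundant in the lists named after other tissues were DNMT3B at 23.8 and 14.5 (pluripotency), EGFL7, a leading gene of pre-B lymphocytes here, at 47.8 and 60.5 (endothelial), SERPINA1 at 22.4 and 29.8 (endoderm), EPCAM at 2.11 and 9.53 (epithelial), MAP2 at 1.34 and 0.965 (neural) and IGFBP3 at 6.61 and 4.59 (trophoblast). For STAB1 (venous), at 2.39 and 1.21, empty droplets gave 4.73 and 3.21, and for MESP1 (early mesoderm), at 1.20 and 3.02, they gave 3.38 and 1.07.

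Mouse cells of the same marrow were mainly erythroid, with erythroblasts at 44.7% (43.5 to 45.8%) of 6951 cells in L1 and 48.1% (46.9 to 49.2%) of 7276 in L5, and erythrocytes at 30.4% (29.3 to 31.5%) and 29.8% (28.8 to 30.9%). Neutrophils were 18.9% (18.0 to 19.8%) and 16.5% (15.7 to 17.4%), monocytes and dendritic cells 4.07% (3.62 to 4.56%) and 4.21% (3.76 to 4.69%), and promyelocytes 2.01% (1.70 to 2.37%) and 1.33% (1.08 to 1.62%). In CPM of the mouse alignment, Hbb-bs was at 229753 and 239106, the neutrophil genes S100a9 and Ngp at 23680 and 9235 and 5020 and 4990, Lyz2 at 1870 and 1894, Cd74 at 146 and 319 and the basophil gene Prss34 at 49.4 and 24.0. Lymphoid and other genes were low, with Ighm at 13.8 and 11.4, Nkg7 at 47.7 and 49.0, Cdk6 at 22.4 and 28.5 (stem and progenitor), Pf4 at 25.1 and 31.5 and Pecam1 at 1.52 and 1.22.

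EB blood cells (mostly MEP) and human marrow cells (mostly B lineage) were set side by side without a test. Tissue, chemistry, genome build and annotation differ too, and mouse RNA may add to marrow HBB. EB blood cells, as mean ± SD CPM in n = 8 libraries, had HBE1 at 6832 ± 3830, HBG2 at 3027 ± 1108 and HBB at 4.91 ± 2.08. Their platelet genes PF4 and PPBP were at 2077 ± 1407 and 2981 ± 2522, GATA1 at 201 ± 25.04 and GFI1B at 146 ± 41.3, against 1.34 and 22.6 of GATA1 in marrow of L1 and L5. RUNX1 was at 75.5 ± 11.8 in EB blood and 60.7 and 56.2 in marrow. CXCR4 was at 4.81 ± 6.14 in EB blood, MYB at 23.3 ± 11.8 and CD79B at 15.0 ± 2.35.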

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

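The comparison of blood with endothelium was chosen only after the separate results had been seen, and so was the look at barcodes without a class. The change from day 13 to day 19 differed between blood and endothelial cells for 141 of 11877 genes (edgeR, adjusted p under 0.05), 103 with the larger value in blood and 38 with the larger value in endothelium, and 1352 genes had an unadjusted p under 0.05. The genes here were named after their values were seen. Log2 fold changes in blood and then endothelium were 1.99 and -0.37 for the antigen presentation gene HLA-B (difference 2.37 ± 0.18, adjusted p = 8.01e-10), and 1.24 and -0.15 for HLA-C. CD9, a tetraspanin of platelets, had 2.20 and 0.19, and the lysosomal protease gene CTSB 1.56 and -0.12. KDR had -1.99 and 0.07 (difference -2.07 ± 0.29, adjusted p = 8.41e-05), and BAALC -1.22 and 1.39. Monocytes went from 5.60% to 28.2% of blood cells, and whether this gave the differences was not tested.

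A signal also stood in barcodes that enter only the alternative with all deposited barcodes. Day 15 replicate 1 has 3753 deposited barcodes, of which 75.8% were named by the authors, and the unnamed ones had a median of 1304 UMIs. In these, CGA, the hormone subunit gene of trophoblast, was at 124.6 CPM (383 UMIs), against 1.74 CPM in the named cells of the same library (71.6-fold higher). Liver genes were higher there too, FGA 7.08-fold, FGB 5.08-fold, AFP 5.07-fold and TTR 4.69-fold, as was the mitochondrial gene MT-CO1 at 3.45-fold, while HBE1 was 0.0751 times its level in named cells.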

How the results depend on the processing

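The alternatives with the highest Scrublet scores left out, MEP cells only, GJA5+ Endothelium only, the block with an estimated correlation, every line of the marrow tables and the larger number of UMIs were chosen only after the results had been seen. For day 19 against day 17 the 2 genes became 333 with the DESeq2 test, 144 with no filter on low counts, 6 with the replicate block, 4 with all deposited barcodes and 22 with the highest Scrublet scores left out. With the replicate block the counts were 6818 for any day and 4820 for day 19 against day 13. In blood the any-day count was 711 with the DESeq2 test and 2143 with no filter, and day 19 against day 13 gave 434 with DESeq2. In endothelium no filter gave 742 for any day and 240 for day 19 against day 13, and GJA5+ Endothelium alone gave 89. OLFML3 turned to -0.50 in GJA5+ Endothelium alone. Lists called fell from 16 to 0 with an estimated correlation and to 0 with the replicate block and an estimated correlation. With each library left out in turn, counts ran from 4284 to 7895 for any day, 4088 to 7894 for day 15 against 13, 1116 to 5162 for day 17 against 15, 0 to 426 for day 19 against 17, and 2199 to 5779 for day 19 against 13. In blood day 19 against 13 ran from 242 to 1003, in endothelium any day ran from 42 to 345 and day 19 against 13 from 12 to 109, and class shares called from 0 to 7. Leaving out 1 library leaves that day with a single library, and for these and the other values that did not hold the cause was not tested. In marrow a species threshold of 80% gave 0.555% human in L1 and 14.3% in L5, because the median human cell had under 80% of its UMIs from the human genome, and 95% left no cells. Counting every line gave 36.5% human in L1, and in L5 53.8% B lymphocytes, 21.2% pre-B lymphocytes, 11.98% monocytes, 4.02% T lymphocytes, 3.56% plasmacytoid cells and 2.04% mast cells. The counts of the whole-EB comparisons other than day 19 against 17 stayed within 1.5-fold with DESeq2, no filter, the block, all barcodes, high scores out and globins out. With the 4 cells that Scrublet called doublets left out, counts were 7769 for any day, 7636, 4455 and 2 for consecutive days, 5402 for day 19 against 13, 1257 in blood and 146 in endothelium for any day, and 6 class shares. Of the named genes, 235 kept their side of the threshold with the DESeq2 test, 19 lost the call and 4 gained it. With 1 library left out calls were lost and gained, and 0 called values changed sign. Not run were Leiden resolutions, since the authors' classes were used, and all barcodes within blood and endothelium, since the added barcodes have no class. Depth limits the blood and endothelial sums, which held 878496 to 3307750 and 836299 to 6018420 UMIs per library.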

Other observations

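All tests here were chosen after the results were seen, except the depth test, the test of RNA from other cells and the granulocyte share test. The condition on quartiles in the granulocyte share test was not part of its prediction. Levels in the endothelial classes are CPM pooled over all cells and days of a class, for genes chosen after their values were seen and without a test, and the classes are spread differently over the days. GJA5+ Endothelium had more of the arterial genes DLL4 (294 against 20.2 in APLNR+ Endothelium), GJA5 (359 against 32.1) and CXCR4 (660.1 against 34.8), and more of MECOM, a stem cell factor (215 against 27.4). In APLNR+ Endothelium the higher values were those of TAL1 (34.8 against 16.2), GFI1B (7.002 against 0.901) and RUNX1 (11.95 against 5.59). CD34 was at 237 in GJA5+ and 162 in APLNR+ Endothelium, 29.1 in MEP cells and 3.94 in Monocytes. MEP cells had the embryonic globin HBE1 at 7391, PF4 at 3184 and GFI1B at 199, and HOXA9 at 1.67 against 21.2 in GJA5+ Endothelium.

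Day 17 replicate 2 lay nearer day 13 in class composition than day 17 replicate 1 did, with dissimilarities from day 13 replicate 1 of 35.1% and 54.4%, and the libraries of day 17 differed by 26.6% from each other, which is less than the 29.2% between those of day 13. A mixture with day 13 cells, or a wrong label, would have had to bring Endoderm cells: at the 57.4% of day 13 cells that the Neural Crest share needs, 5.90% of cells would be Endoderm, but 1.32% were (95% exact interval 0.931 to 1.81%). Depth per cell was tested on cells of 5000 to 20000 UMIs, among which the day 17 libraries still differed by 27.9% (day 13, 29.9%), so depth is unlikely to be the whole cause. No biological explanation was tested, since both libraries belong to the same group, and a culture that developed differently or a difference in preparation stays open.

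Platelet and myeloid genes were higher in EB blood cells on day 19, when Monocytes were a larger share of those cells. For megakaryocyte genes a larger share of Monocytes cannot be the whole cause, since in MEP cells alone the list's median log2 fold change was 1.95 and Monocytes named MEP would lower it, and RNA from other cells is unlikely, since the rise outside the blood classes was 0.185% of that within them. For granulocyte genes the observed change minus that given by the Monocyte share had a median of -0.31. Members went both ways, from -0.92 (PRTN3) to 1.42 (S100A8), with quartiles of -0.46 and 0.85. The median alone met the bound set in advance for the share as the cause. The upper quartile, a condition absent from that prediction, did not, so the share was left open. The granulocyte median of 5.67 in MEP cells alone, where 3 of 6 rose, leaves it open too, since Monocytes named MEP would raise these genes. For monocyte and macrophage genes the same difference was 0.97 (quartiles 0.45 to 2.21), which rests on 12 Monocytes of day 13 and leaves the share open, and so does a median of 1.16 in MEP cells alone, for the same reason. The difference for monocyte and macrophage genes argued against the share when first computed with fitted fold changes of CD14 and FCGR3A, which had 0 UMIs on day 13, before a bound was used for them, and a change in MEP cells, misnamed cells among them or a difference in preparation stays open as an untested hypothesis.

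HBB was counted in human marrow cells outside the erythroid class, and mouse cells aligned to the human genome gave HBB counts as well. In L1 the ratio of HBB to HBD in these cells differed by 1.03-fold from that in mouse cells, in line with mouse globin RNA as the source, and the ratio of HBA1 and HBA2 to HBB was 0.0176 of that in human erythroid cells, which argues against free human erythroid RNA, but 2.15-fold that in mouse cells, which leaves open whether mouse RNA was the only source. In L5 the same values were 1.27 and 0.259, between the bounds set for each, but HBA1 and HBA2 relative to HBB were 38.7-fold the ratio in mouse cells, which argues against mouse RNA as the only source and leaves free human erythroid RNA and a mixture of both open. In the erythroid class of L5, HBA1 and HBA2 relative to HBB were 149-fold the ratio in mouse cells, so mouse RNA is unlikely to be the source of its globin counts. The tests were first made over both mice and then split by mouse once the values had been seen, and no biological explanation was tested.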
